A study of Mus musculus with 6 samples.

How the data were processed

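Gene expression was measured on 6 Affymetrix Mouse Genome 430 2.0 arrays of tumour epithelial cells sorted from benign skin papillomas of mice. The papillomas had been induced chemically, and the mice had received tamoxifen for 1 week. In the Sox2cKO mice a Cre recombinase driven from the keratin 14 promoter and switched on by tamoxifen deletes the floxed Sox2 gene, and the control mice were given tamoxifen as well. Per the labels' protocols, tumours were digested with collagenase I and living single cells were sorted for Epcam and alpha6 integrin. Cells carrying CD45, CD31 or CD140a, the surface markers of leukocytes, endothelium and fibroblasts, were excluded. RNA was extracted with the RNeasy micro kit, and 100 ng of total RNA with bacterial spike-in transcripts was amplified and labelled with biotin by the GeneChip 3' IVT Express kit, per the labels' protocols. Such amplification starts at the poly-A tail, so each value reads the 3' end of its transcript.

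The deposited values are on a log2 scale, with 1 value per probe set and array, read so from their range because no source used here names the scale. Per the submitters' processing notes, the authors used R 2.14.0. The background correction, the summarising method and the normalization between arrays were not given in the sources used here. The table held 45101 probe sets, of which 64 were Affymetrix controls, and no value was missing. Array medians lay between 5.42 and 5.46, so the arrays had been brought to a common scale before deposit. A mean shift of expression shared by most genes would therefore not be seen. For low genes the values flatten towards background, which lay near 3.4 (3.30 to 3.44) for unspiked bacterial control probe sets, so large differences that reach down to that level are understated. No scanner output was analysed here.

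Probe sets were named through the platform annotation. Of 45037 mouse probe sets, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed. Symbols were checked through their Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which was used for names and gene order, and 0 needed updating. Probe sets with several genes or none were left out of the gene tests and counted on their own. A probe set was tested where at least 3 of the 6 arrays exceeded that array's 40th percentile (4.90 to 4.94). This left 27462 probe sets, 23534 of them with 1 gene, and 13222 genes. Each gene was represented by its probe set with the highest mean over all 6 arrays, a choice that mattered for the 6019 genes with more than 1 tested probe set.

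The groups were 3 control and 3 Sox2cKO arrays, and the series' design text speaks of 3 biological experiments. Differences are Sox2cKO minus control on the log2 scale. They were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p given for a gene is from this test unless another is named. For single values an exact two-sided permutation test of group means was used, which cannot go below 0.1 for 3 arrays against 3. The number of arrays limits the precision.

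Gene lists were tested with camera from limma, with a preset inter-gene correlation of 0.01 and adjustment over lists. Of 41 lists fixed before the data were examined, 32 described keratinocyte layers, signalling, cell cycle, stress and metabolism, and 9 held markers of cell types the sort could contain. The 40 lists with at least 5 tested members were tested. Camera with the correlation estimated per list, and fry, which tests whether the genes of a list move one way on balance, were run as alternatives. Scores per array are means of each member's log2 value after subtracting its mean over the 6 arrays.

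The genes named in the text follow a rule that was also fixed beforehand. It takes Sox2 first. It then takes 12 genes in each direction past the threshold with groups apart, meaning that all 3 values of a group lie above all 3 of the other. Places left open go to the genes of smallest unadjusted p with groups apart and a fold of at least 1.5, unnamed clones excluded, given as values that did not pass. From each list it takes up to 3 members of smallest unadjusted p, and last the sort markers Epcam, Itga6, Ptprc, Pecam1 and Pdgfra. Other genes in the text were named after their values were seen.

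The labels give replicate numbers 1 to 3 in both groups without saying what a number marks. Arrays of the same number deviated together from their group means (correlation across genes 0.206 to 0.288 for the 3 pairs, against -0.333 to 0.06 for arrays of other numbers in opposite groups). Every pair exceeded 0.1, the level set for treating the numbers as pairs, so the fit with the replicate number as a block is printed where it changes a call or moves a count by more than 1.5 times. No pair of arrays held identical values.

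The procedure was tested on simulated data of 13222 genes, of which 200 were changed. The noise was independent between genes and arrays, with each gene's spread drawn from the distribution that limma fitted. It recovered 2% of genes changed by 0.5 on the log2 scale, 50% of those changed by 1, and 100% of those changed by 2 or 4, and 5.26% of its calls were unchanged genes. These shares do not carry over to real arrays that vary together, where Sox2, at -3.92, had an adjusted p of 0.316 in limma. For lists, a simulated shift of 0.5 was called in 20 of 20 rounds. Unshifted lists were called in 0.273% of tests with independent genes and in 37.4% when genes of a list shared a factor, so a camera call with the preset correlation is weak evidence where list members vary together. Camera with an estimated correlation was not simulated, so how often it would call a shifted list is not known.

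Alternatives were the replicate block, leaving out each array, quantile normalization of the table, no intensity filter or a stricter one (mean above the 60th percentile), the mean of a gene's probe sets, leaving out _x_at and _s_at probe sets, every probe set on its own, a trended robust fit, array weights, an adjusted p under 0.1, and log2 of the linear value plus 16. After the data were seen, a sex covariate, arrays with low Xist only, genes outside the X and Y chromosomes, and the block together with the sex covariate were added, as was the count of genes at an unadjusted p under 0.05. An estimated correlation was then also used with these sex terms, the low-Xist arrays, the replicate block and each array left out, and in every other setting where a further list passed.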

Results

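Tumour epithelial cells from chemically induced papillomas were compared between Sox2cKO and control mice after 1 week of tamoxifen, with 3 arrays per group. Sox2 is a transcription factor of stem and progenitor cells, and the comparison asks which genes of benign tumour cells change when it is deleted. Correlations between arrays over the 13222 genes tested lay between 0.966 and 0.990, and the highest was between control replicate 1 and Sox2cKO replicate 1. The median SD of a gene within groups was 0.19 on the log2 scale.

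Sox2 itself read lower in Sox2cKO cells, by 15.1-fold in the deposited values, where the Sox2cKO signal lay near background. Its only probe set (1416967_at) read 7.90 ± 0.61 in controls and 3.98 ± 0.70 in Sox2cKO (mean ± SD, n = 3 each), a log2 difference of -3.92 with a standard error of 0.41. Controls read 7.19, 8.31 and 8.18, and Sox2cKO arrays read 4.07, 4.63 and 3.23. All 3 Sox2cKO arrays fell below the array's 40th percentile, and 0 of the control arrays did. Background lay at 3.30 to 3.44, so the size of the difference is limited by it, and with 16 added on the linear scale the log2 difference was -2.98. Sox2 had the smallest unadjusted p of all genes in limma (2.39e-05), but its adjusted p over 13222 genes was 0.316. Adjusted over the list alone, that of SOX and pluripotency-associated regulators, it was 0.000454. The exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. Whether the probe set lies in the deleted part of the gene was not examined here. Without control replicate 1, Sox2 passed the threshold (log2 difference -4.27, adjusted p 0.0425).

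**Figure D1:**
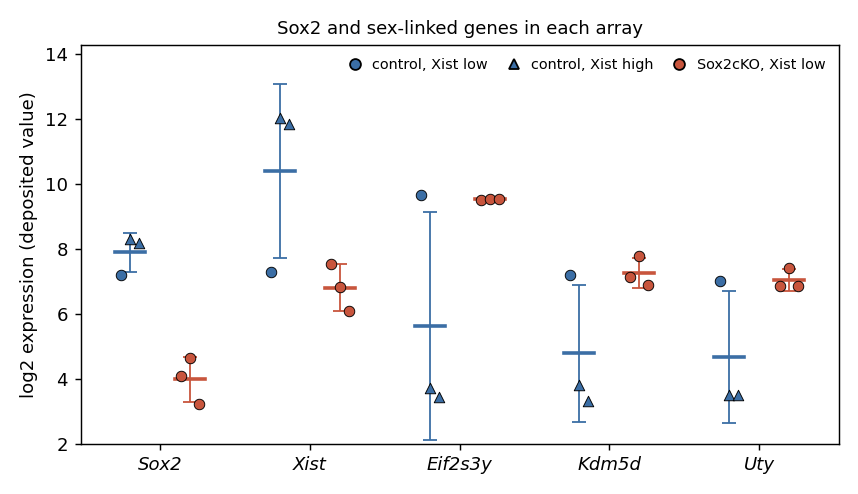
Deposited log2 values of Sox2 and of sex-linked genes in each array, with points for arrays, horizontal lines for group means and bars for SD (n = 3); triangles mark arrays with high Xist. Sox2 reads 7.19 to 8.31 in controls and 3.23 to 4.63 in Sox2cKO, and controls 2 and 3 have Xist near 12 with low Y-linked genes.

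The arrays also differed in sex-linked genes. Xist, the RNA that coats the inactive X chromosome of females, read 12.03 and 11.85 in control replicates 2 and 3, and 6.08 to 7.54 in the other 4 arrays. The Y-linked gene Eif2s3y read 3.72 and 3.45 in those 2 controls and 9.52 to 9.67 elsewhere, and Kdm5d and Uty followed the same division. Thus 2 of the 3 control arrays and 0 of the 3 Sox2cKO arrays had a female pattern, and control replicate 1 is the only control with the male pattern of the Sox2cKO arrays.

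Among genes with groups apart, the largest gains were in Gypc and Stfa2l1 and the largest loss after Sox2 was in Pde3b, but none of these passed the adjusted threshold. Gypc, which encodes the membrane sialoglycoprotein glycophorin C, read 5.36 ± 0.63 in controls and 8.22 ± 0.71 in Sox2cKO, 7.30-fold higher. Stfa2l1, of the stefin A family of cysteine protease inhibitors, read 6.67 ± 1.17 and 8.97 ± 0.49. The serotonin transporter gene Slc6a4 (log2 difference 0.98), the ERK phosphatase gene Dusp2 (1.30), the deacetylase gene Sirt1 (0.70) and the epithelial transcription factor gene Ovol2 (0.61) were also higher in every Sox2cKO array than in every control array. So were Tent5c (0.80), Gapdhs (0.82), Tcp11l2 (0.66) and C1qtnf2 (0.61). Rhbdl2 (1.51) and the imprinted non-coding RNA Meg3 (0.59) complete the 12 higher genes, but the 2 other tested probe sets of Rhbdl2 pointed the opposite way, at -0.28 and -0.42. Of the 7 other tested probe sets of Meg3, 2 pointed the opposite way (-0.23 and -0.11) and 5 the same way (0.06 to 0.82).

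Among lower genes, Pde3b, a phosphodiesterase that breaks down cyclic AMP, read 7.19 ± 0.76 in controls and 4.99 ± 0.47 in Sox2cKO, 4.62-fold lower. Adgrg6, an adhesion G protein-coupled receptor, differed by -1.41, and its second tested probe set pointed the same way. Ces1g (-1.38), which encodes a carboxylesterase, and the Polycomb gene Cbx6 (-1.38) were lower by 2.61-fold each. The Wnt5a receptor gene Ror2 (-0.83), the phospholipid scramblase gene Plscr1 (-0.90), the casein gene Csn1s1 (-0.91), the centromere protein gene Itgb3bp (-0.75) and the granzyme B inhibitor gene Serpinb9 (-0.63) followed. The MHC class II chain gene H2-Ab1 read 9.13 ± 0.16 in controls and 7.87 ± 0.62 in Sox2cKO, and H2-DMa, which loads peptides onto class II molecules, differed by -0.84. Standard errors of the 11 lower genes after Sox2 lay between 0.13 and 0.40, and those of the 12 higher genes between 0.13 and 0.55.

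**Figure D2:**
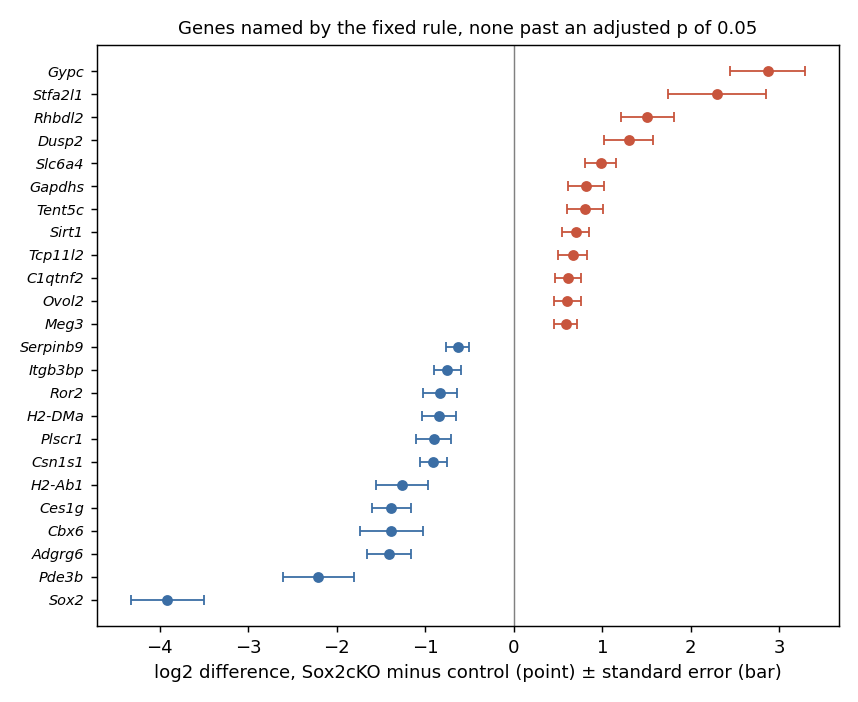
Log2 difference (Sox2cKO minus control, point) with its standard error (bar) for the 12 higher and 12 lower genes taken by the fixed rule. Differences run from -3.92 for Sox2 to 2.87 for Gypc, and no gene had an adjusted p under 0.05.

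Across all 13222 genes, 0 had an adjusted p under 0.05 in limma. The lowest after Sox2 was 0.999. At an unadjusted p under 0.05 there were 354 genes (183 higher and 171 lower), fewer than the 661 that chance gives on average, and with the replicate number as a block there were 656. Groups were apart in 773 genes (5.85%, where chance gives 10%), and 101 of these differed by at least 1.5-fold, 60 higher and 41 lower. Without control replicate 1, 5 genes passed, which were Sox2 and the sex-linked genes Xist, Eif2s3y, Kdm5d and Uty. With a sex covariate 1 gene passed, Ostf1, which read 4.41 in control replicate 1 and 8.44 to 9.28 in the other arrays.

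The sort markers described the cells. Itga6, the alpha6 integrin gene, read 12.17 ± 0.07 in controls and 12.26 ± 0.19 in Sox2cKO. Epcam read 11.31 ± 0.20 and 10.85 ± 0.35. Of the markers of excluded cells, Ptprc (CD45) read 5.00 ± 0.27 and 5.10 ± 0.48, and Pecam1 (CD31) read 4.58 ± 0.11 and 4.73 ± 0.21 and failed the intensity filter. Pdgfra (CD140a) read 5.30 ± 0.24 in controls and 6.32 ± 0.89 in Sox2cKO. None of these 5 differences passed the threshold.

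Of the 40 gene lists tested, 10 passed an adjusted p of 0.05 with camera, 5 higher and 5 lower in Sox2cKO cells. With an estimated correlation 0 lists passed, and with fry 0 passed (lowest adjusted p 0.596). No list member passed over all genes, and 2 passed adjusted over the list alone, Sox2 and the ribosomal protein gene Rps6 (log2 difference 0.55). With the sex covariate 5 lists passed, 3 of them among the 10, and 0 passed when the correlation was estimated as well. The sex covariate, like the fit of low-Xist arrays only, sets the Sox2cKO arrays against control replicate 1 alone and takes the spread from the other arrays. The block with the sex covariate compares Sox2cKO replicate 1 with control replicate 1 and takes the spread from the other arrays, so its medians are given below as values without a test.

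Markers of fibroblasts and pericytes were higher in Sox2cKO as a group. Of 18 tested members 16 were higher, with a median log2 difference of 0.94 (adjusted p = 9.43e-11, and adjusted p = 0.630 with an estimated correlation). The collagen and proteoglycan genes Dcn (7.70 ± 0.81 in controls, 9.43 ± 1.21 in Sox2cKO), Lum (6.98 ± 0.75 and 8.59 ± 0.97) and Col5a1 (7.18 ± 0.34 and 8.05 ± 0.55) had the smallest unadjusted p values. None of the 18 genes passed over all genes tested, and 0 passed adjusted over the list alone. The scores were 0.08, 0.12 and 1.06 in Sox2cKO and -0.26, -0.18 and -0.81 in controls (exact permutation p = 0.1). Pdgfra, whose product was used to exclude cells from the sort, is a member. Against control replicate 1 alone the median was 0.75, and between Sox2cKO and control replicates 1 it was 0.19. Without Sox2cKO replicate 3 it was 0.55 (7.80e-07), with Dcn at 1.10, Col5a1 at 0.55 and Pdgfra at 0.55, and the 18S ribosomal RNA signal read 12.49 in that array and 10.96 to 11.78 in the others.

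Cell cycle genes were lower as a group. In the list of G2 and mitosis 28 of 29 tested genes were lower, with a median of -0.26 (adjusted p = 2.49e-10, and adjusted p = 0.630 with an estimated correlation). The spindle genes Nusap1 (-0.35) and Kif11 (-0.25, with its other tested probe sets at -0.28 and 0.06) and the CDK1-activating phosphatase gene Cdc25c (-0.61) were lower in every Sox2cKO array than in every control array. Only these 3 of the 29 genes had groups apart, where chance gives 10%. The list score of Sox2cKO replicate 3 was 0.15, and those of control replicates 1 to 3 were -0.04, 0.34 and 0.11. In the list of DNA replication and S phase 26 of 27 genes were lower, with a median of -0.21 (adjusted p = 6.60e-07, and adjusted p = 0.630 with an estimated correlation). Its leading members were the thymidine kinase gene Tk1 (10.01 ± 0.29 and 9.50 ± 0.10), the replication helicase gene Gins2 (-0.28) and the chromatin assembly gene Chaf1b (-0.33). No member of either list passed over all genes or adjusted over the list alone, with 0 of 29 and 0 of 27. Neither list passed with the sex covariate, at medians of -0.08 and -0.10 (adjusted p 0.0991 and 0.0945), or -0.10 and near 0 between replicates 1, and without Sox2cKO replicate 2 the medians were -0.14 (0.0435) and -0.07 (0.291), with Chaf1b at -0.19. Without control replicate 2 they were -0.16 and -0.13 (8.73e-06 and 8.09e-05), with Cdc25c at -0.38, and without Sox2cKO replicate 3 that of G2 and mitosis was -0.40. The exact permutation p of the list score was 0.3 for G2 and mitosis and 0.2 for S phase.

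Genes of the unfolded protein response were slightly higher, 21 of 23, with a median of 0.13 (adjusted p = 0.000450, and adjusted p = 0.630 with an estimated correlation). The correlation estimated for this list was 0.015, close to the preset 0.01, while the median over lists was 0.166 and the highest 0.688. The higher adjusted p of this list is thus not shown to come from members that vary together. The endoplasmic reticulum co-chaperone gene Dnajb9 read 9.79 ± 0.47 in controls and 10.60 ± 0.23 in Sox2cKO, the pseudokinase gene Trib3 differed by 0.41 and the disulfide isomerase gene Pdia4 by 0.28 (-0.06 in its other tested probe set). With the sex covariate, which compares with control replicate 1 alone, the median was 0.15. Without Sox2cKO replicate 3 the list did not pass (median 0.09, 0.105). Interferon response genes were higher in 20 of 25, with a median of 0.29 (adjusted p = 0.000450, and adjusted p = 0.653 with an estimated correlation). Ifit1 (4.45 ± 0.31 and 5.61 ± 0.60), the peptide transporter gene Tap1 (0.54, but -0.21 in its other tested probe set) and Irf7 (0.44) led this list. Its score was highest in Sox2cKO replicate 2 (0.76), without which the median was 0.01 and the adjusted p 0.873, with Tap1 at 0.33, and with the sex covariate the median was 0.06 (0.885). It was 0.60 without Sox2cKO replicate 3 and -0.20 between replicates 1, and Irf7 was at 0.29 without control replicate 2. For the list scores the exact permutation p was 0.1 for the unfolded protein response and 0.6 for the interferon response.

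Suprabasal keratinocyte genes were higher against the mean of all 3 controls and lower against control replicate 1 alone. The exact permutation p of the list score was 0.4 for the markers and 0.6 for the differentiation list. All 10 markers of suprabasal keratinocytes were higher, with a median of 0.36 (adjusted p = 0.00231, and adjusted p = 0.630 with an estimated correlation). In the list of suprabasal differentiation and cornified envelope 19 of 23 were higher, with a median of 0.19 (adjusted p = 0.00572, and adjusted p = 0.678 with an estimated correlation). The cornified envelope genes Ivl (7.32 ± 0.86 and 8.16 ± 0.11) and Lor (0.33), the protease gene Asprv1 (0.47) and Sbsn (0.39) led these lists. With the sex covariate the medians turned to -0.32 and -0.20 and neither list passed (0.295 and 0.0945), and Ivl turned to -0.13. Between replicates 1 they were 0.15 and 0.12. Neither list passed without control replicate 2 (0.133 and 0.406), control replicate 3 (0.0834 for both) or Sox2cKO replicate 1 (0.204 and 0.641). The medians were 0.19 and 0.07 without control replicate 2, 0.29 and 0.14 without control replicate 3, 0.13 and 0.07 without Sox2cKO replicate 1, 0.54 and 0.48 without control replicate 1, and 0.66 and 0.35 without Sox2cKO replicate 3. Ivl differed by 0.50 and Asprv1 by 0.27 without control replicate 3, and Ivl by 1.32 without control replicate 1.

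Lipid genes were lower as a group, 16 of 19 in the list of fatty acid synthesis and sebaceous gland, with a median of -0.31 (adjusted p = 0.000395, and adjusted p = 0.630 with an estimated correlation). Markers of sebocytes, the lipid-filled cells of sebaceous glands, were lower in 6 of 7, with a median of -0.40 (adjusted p = 0.0118, and adjusted p = 0.630 with an estimated correlation). Lipoprotein lipase gene Lpl (7.74 ± 0.67 and 6.91 ± 0.38), Mgst1 (-0.40), Elovl5 (-0.34), Elovl3 (-1.65) and Far2 (-1.43) were the leading members. The sebocyte score was 1.06 in control replicate 2 and -0.05 and -0.06 in the other controls. Without control replicate 2 the fatty acid list had a median of -0.14 (0.0206), and Elovl3 differed by -0.77, Far2 by -0.64 and Lpl by -0.45. Without Sox2cKO replicate 3 Elovl3 differed by -1.09, Far2 by -0.91 and Mgst1 by -0.24. Without control replicate 2 the sebocyte list did not pass (median -0.14, 0.230), nor without Sox2cKO replicate 1 (median -0.41, 0.123) or 3 (median -0.24, 0.184), while without Sox2cKO replicate 2 its median was -0.89, and with the sex covariate neither lipid list passed (medians -0.07 and -0.25, 0.769 and 0.532). Between replicates 1 the medians were -0.18 and -0.34. Inflammatory genes of the NF-kB list were lower in 20 of 28, with a median of -0.12 (adjusted p = 0.0383, and adjusted p = 0.630 with an estimated correlation). Csf2 (-0.62), Tnfaip2 (-1.29) and the chemokine gene Cxcl2 (-0.72) led it. Cxcl2 differed by -0.20 without Sox2cKO replicate 2, Csf2 by -0.37 without control replicate 2, and Tnfaip2 by -0.80 and -1.97 without Sox2cKO replicates 1 and 3. The list did not pass without control replicate 1 (median -0.10, 0.244), control replicate 3 (median -0.11, 0.0834) or Sox2cKO replicate 2 (median -0.04, 0.965). With the sex covariate, which compares with control replicate 1 alone, its median was -0.29, and that control had the highest score of the 6 arrays (0.25). The median was -0.20 without control replicate 2, -0.28 without Sox2cKO replicate 1 and 0.02 between replicates 1. For the list scores the exact permutation p was 0.3 for the fatty acid list, 0.4 for sebocyte markers and 0.5 for the NF-kB list.

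**Figure D3:**
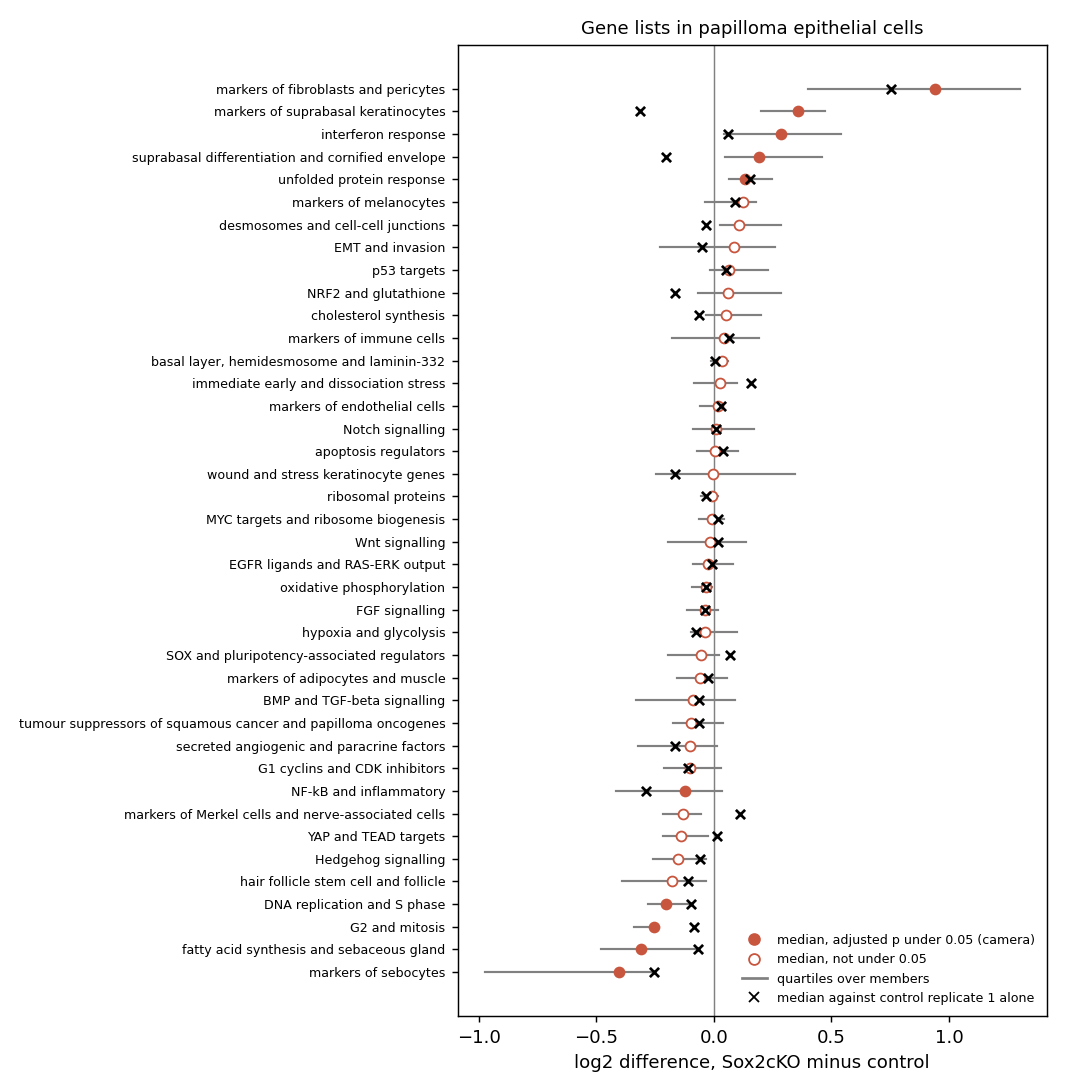
Median log2 difference (Sox2cKO minus control) of the tested members of 40 gene lists, with quartiles over members; filled points passed an adjusted p of 0.05 with camera, and crosses give the median against control replicate 1 alone. Fibroblast and pericyte markers lie highest at 0.94, and the suprabasal lists change sign, from 0.36 to -0.32 and from 0.19 to -0.20.

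**Figure D4:**
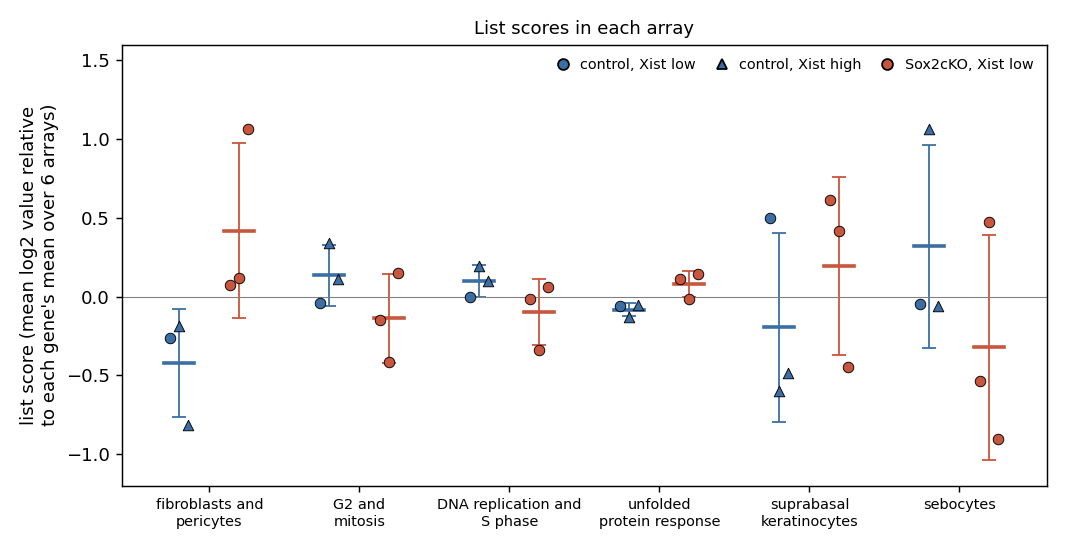
Score of 6 lists in each array (mean log2 value relative to each gene's mean over 6 arrays), with lines for group means and bars for SD (n = 3); triangles mark the arrays with high Xist. Sox2cKO arrays read 0.08 to 1.06 and controls -0.81 to -0.18 for fibroblast and pericyte markers, while suprabasal scores of the groups overlap.

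The other 30 lists did not pass, with medians between -0.18 and 0.12. Hedgehog genes came closest (median -0.15, adjusted p 0.0702), with Cdon at -0.43, and passed with the replicate block (0.0453), but the adjusted p with an estimated correlation was 0.666 with that block and 0.630 without it, and the median was -0.06 (0.999) with the sex covariate. Basal layer genes had a median of 0.03 (adjusted p 0.911), with Krt15, a keratin of basal and follicle stem cells, at -0.56, and hair follicle genes a median of -0.18 (0.124). The SOX and pluripotency-associated list had a median of -0.05 (0.124), with Prom1, a surface marker of stem-like cells, at -1.45 ± 0.78 (standard error). Wound keratinocyte genes had a median near 0 (0.696), with Lcn2, an iron-binding secreted protein gene, at -1.13. Notch genes had a median of 0.01 (0.911), Wnt genes -0.02 (0.751) with the Wnt inhibitor gene Notum at -0.52, EGFR and RAS-ERK genes -0.03 (0.911), FGF genes -0.04 (0.622), and BMP and TGF-beta genes -0.09 (0.191). The p53 targets had a median of 0.07 (0.0814) with Trp53inp1 at 0.64, and apoptosis regulators 0.01 (0.949). Cell junction genes had a median of 0.11 (0.138), YAP targets -0.14 (0.117), G1 cyclins and CDK inhibitors -0.10 (0.101), and tumour suppressors and oncogenes of squamous tumours -0.10 (0.124) with Cdkn2a at -0.76. EMT and invasion genes had a median of 0.08 (0.261), with the collagen crosslinking enzyme gene Lox at 0.66 and the integrin gene Itga5 at -0.95 (-0.62 to -0.06 in its other tested probe sets). Secreted angiogenic and paracrine factors had a median of -0.10 (0.197), immediate early genes 0.02 (0.911), and NRF2 and glutathione genes 0.06 (0.328). These last 2 lists passed with the sex covariate, at medians of 0.16 (0.000170, and adjusted p = 0.819 with an estimated correlation) and -0.17 (0.00370, and adjusted p = 0.599). That fit rests on control replicate 1, whose scores of -0.21 and 0.29 were the lowest and the highest of the 6 arrays, and without it the NRF2 median was 0.14. Cholesterol synthesis had a median of 0.05 (0.328), hypoxia and glycolysis -0.04 (0.848), oxidative phosphorylation -0.03 (0.142), MYC targets -0.01 (0.841) and ribosomal proteins -0.01 (0.911). Endothelial markers had a median of 0.02 (0.916) melanocyte markers 0.12 (0.487), Merkel and nerve-associated markers -0.13 (0.328), and adipocyte and muscle markers -0.06 (0.911). Markers of immune cells had a median of 0.04 but a mean of -0.16 (0.536), with H2-Aa at -1.38 and Cd74 at -1.09. Median and mean also differed in sign in the hypoxia, wound, Wnt, EGFR and endothelial lists, where the test took the sign of the mean for hypoxia and wound genes and of the median for the others.

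Of these 30 lists, 16 passed in some other setting with the preset correlation, and with an estimated correlation 0 lists passed in any of those settings (lowest adjusted p 0.469). Without control replicate 1 the lists that passed were Hedgehog genes (median -0.26, adjusted p 0.0202), cell junction genes (0.19, 0.0202), p53 targets (0.18, 0.0441), NRF2 and glutathione genes (0.14, 0.00726), the SOX list, which holds the deleted Sox2 itself (-0.17, 0.0200), and YAP targets (-0.18, 0.0441). Without control replicate 3 oxidative phosphorylation passed (-0.10, 0.0300), and without Sox2cKO replicate 1 BMP and TGF-beta genes (-0.09, 0.0409) and p53 targets (0.12, 0.00556). Without Sox2cKO replicate 2 basal layer genes (0.13, 0.0194), EMT and invasion genes (0.13, 0.00707), hair follicle genes (-0.16, 0.0302) and Hedgehog genes (-0.25, 0.0290) passed. Without Sox2cKO replicate 3 melanocyte markers (0.45, 0.00471), cell junction genes (0.19, 0.00560) and the SOX list (-0.08, 0.0222) passed. Hedgehog genes also passed without an intensity filter (0.0452) and with the stricter one (0.0265), as did G1 cyclins and CDK inhibitors with the latter (0.0394), and p53 targets with the mean of probe sets (0.0254). With low-Xist arrays only, immediate early genes (0.000126), NRF2 genes (0.00430), secreted factors (0.0430) and wound keratinocyte genes (0.0214) passed.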

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

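The sex covariate, the low-Xist arrays, the block with the sex covariate, the chromosome filter and the count at an unadjusted p were chosen after the result was seen. The count of 0 genes held under all planned settings over 6 arrays, and Sox2 kept its direction in every setting run (adjusted p 0.0425 to 1.00). Sox2 gave no value under the stricter filter. All 24 higher and lower genes named first, Sox2 included, kept their direction in every setting with 1 value per gene in which they were tested. The rule took only genes with groups apart. Their direction therefore could not turn when arrays were left out or weighted, with the block or the sex covariate, or with 16 added. In those settings the kept direction is no support. Single probe sets of Rhbdl2 and Meg3 pointed the opposite way, as given above. For the counts and Sox2, 70 values kept their side of the threshold or stayed within 1.5 times, while 32 count values moved further and 1 value of Sox2 gained the threshold. Of the 10 lists past the threshold, 140 values kept their side, 172 kept the direction and lost the threshold, most of them with an estimated correlation, and 16 turned direction. Among genes named by the rule 12 values turned direction. Fibroblast and pericyte markers passed in all 18 settings with the preset correlation, 1 of which compares 1 array with 1, but not with an estimated correlation (0.630) or fry (0.731). Of the 30 lists not past it, 26 turned direction and 16 passed in at least 1 setting.

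Without each array in turn, 0 to 5 genes passed, 200 to 637 had an unadjusted p under 0.05, 143 to 443 were apart with a fold of at least 1.5, and Sox2 differed by -4.27 to -3.54. The extremes came without control replicate 1 (5, 637 and 443 genes) and, for 200 and 143 genes, without control replicate 2. Without Sox2cKO replicate 1, 2 or 3, 229, 324 and 269 genes were apart, since 3 against 2 arrays are more easily so, and without replicate 2 the unadjusted count was 632. The unadjusted count was 656 with the replicate block, which changed no other call than that of the Hedgehog list, and 687 for every probe set on its own, where more are tested. With the sex covariate it was 94, with 1 gene and 5 lists past the threshold. With low-Xist arrays only, which leave 1 control, assumed to vary like the Sox2cKO arrays, it was 89, and 224 genes were apart. With the block and the sex covariate, which sets Sox2cKO replicate 1 against control replicate 1, it was 196, and 4 lists passed, with a spread taken from the other arrays. With an estimated correlation 0 lists passed in each of the 14 settings run so, all but 1 of them chosen after the result was seen, and with fry 0.

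With the sex covariate and with low-Xist arrays, suprabasal markers turned to -0.315, suprabasal differentiation to -0.205, Ivl to -0.13 and Ptprc to -0.0450. With the block and the sex covariate, Ivl turned to -0.0362, Tap1 to -0.20, Lum to -0.13, Epcam to 0.17 and Pdgfra to -0.0358, the S phase list to 0.00485, the NF-kB list to 0.0176 and the interferon list to -0.197. Without each array in turn, Ptprc ran from -0.10 (without Sox2cKO replicate 2) to 0.36 and Itga6 from -0.00645 (without Sox2cKO replicate 3) to 0.18. The NF-kB median ran from -0.28 to -0.0384, the latter without Sox2cKO replicate 2, where the test turned upward. The cause was not tested. Signal near background limits Sox2 in Sox2cKO arrays, where adding 16 on the linear scale gave -2.98.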

Other observations

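The tests of fibroblast markers and of cell cycle genes, the choice of MHC class II genes and the use of standard errors in judging the tests came after the result was seen. So did the count at an unadjusted p, while the test near Sox2 and the counts of splits were chosen before their own results. Of MHC class II genes, whose products present peptides to T cells, 5 were picked for their low values in Sox2cKO cells and not tested as a group, and the list of immune cell markers did not pass (0.536). H2-Aa differed by -1.38, H2-Ab1 by -1.26, Cd74 by -1.09, H2-Eb1 by -1.01 and H2-DMa by -0.84, and in H2-Ab1, H2-DMa and Cd74 every Sox2cKO array lay below every control array. Against control replicate 1 alone the differences were -1.85, -1.39, -1.65, -1.37 and -1.18 in the same gene order. Adjusted p was 0.999 for each of the 5 genes. The leukocyte marker Ptprc differed by 0.10.

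Cdk4, the kinase that drives cells through G1, read 10.63 ± 0.13 in controls and 10.36 ± 0.04 in Sox2cKO, the CDK inhibitor gene Cdkn2d differed by -0.32, and Cdkn1a, the p21 inhibitor gene, by 0.40. The list score of G1 cyclins and CDK inhibitors was lower in every Sox2cKO array than in every control array (exact permutation p = 0.1), while the list did not pass (camera adjusted p 0.101, and 0.630 with an estimated correlation). Groups were apart in 6 of 40 list scores, where chance gives 10%, among them that of the SOX list, which holds Sox2 itself. Gt(ROSA)26Sor, the transcript of a locus widely used for reporter insertions, read 8.21, 7.31 and 3.54 in controls and 8.46 to 8.70 in Sox2cKO. The suprabasal marker score divided the arrays regardless of genotype. It was 0.50, 0.62 and 0.42 in control replicate 1 and Sox2cKO replicates 1 and 2, and -0.60, -0.48 and -0.45 in control replicates 2 and 3 and Sox2cKO replicate 3.

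Fibroblast and pericyte markers were higher in Sox2cKO arrays, although CD140a, the product of Pdgfra, was used to exclude fibroblasts from the sort. Sex of the mice stays open, since the median of 0.75 with it as a covariate rests on 1 low-Xist control (standard error of the score difference 0.603), and with the replicate block as well it was 0.19. RNA of stromal cells that passed the sort may contribute. Pdgfra and 8 collagen and proteoglycan genes deviated from their group means together, with a mean pairwise correlation of 0.943 (permutation p = 1e-04, the smallest 10000 permutations can give). Abundant members such as Col1a2 (10.24 in controls, 11.47 in Sox2cKO) and Col3a1 (9.73, 11.08) moved with them, while 3 of the list's genes are also in other lists. The correlation does not single out stromal RNA, since genes changed together for another cause would also correlate. Sox2cKO replicate 3 also stood apart in the list score (1.06, against 0.08 and 0.12 in the other Sox2cKO arrays). A change caused by Sox2 loss in every tumour stays open, since 6 of 18 markers were above all controls in all 3 Sox2cKO arrays.

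Cell cycle genes were lower in Sox2cKO arrays, with a median of -0.24 over the 56 genes of both lists. Dilution by stromal RNA would lower basal epithelial genes alike. As the whole cause of the difference from all 3 controls it is weakly argued against, and not excluded. The median of basal genes was 0.03 (quartiles -0.01 to 0.06, and 0.13 without Sox2cKO replicate 2). Their score differed by 0.03 with a standard error of 0.144, so by itself it does not exclude a fall like that of cell cycle genes. The cell cycle score less the basal score still differed by -0.26 (standard error 0.110, and -0.17 without control replicate 2). It was -0.04, 0.31 and 0.13 in control replicates 1 to 3, and -0.21, -0.10 and -0.07 in Sox2cKO replicates 1 to 3. From control replicate 1, the only low-Xist control, the gap was thus smaller, and it rests on 1 array. Sex of the mice stays open as well, because with it as a covariate the median was -0.0889 and the standard error of the score difference, resting on 1 low-Xist control, was 0.242. The amount of input RNA stays open: over the 6 arrays, with group means removed, the cell cycle score and the level of the poly-A spike-in correlated at Pearson r = 0.701 (exact permutation p = 0.118) and Spearman rho = 0.771 (exact permutation p = 0.103). Without control replicates 1 and 2, r was 0.722 over the other 4 arrays. Their deviations were still taken from the group means of all 6 arrays. The spike-in level was 8.97 ± 0.50 in Sox2cKO and 8.43 ± 1.61 in controls, a difference in the direction opposite to the one this correlation would need, but within the spread of controls, and an effect of Sox2 loss on proliferation stays open as well.

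Donor strain DNA kept around the floxed allele was tested by gene order. Of the 100 tested genes nearest to Sox2, 0 were apart with a fold of at least 1.5, against 100 of 13121 others (0.762%), with a one-sided Fisher exact p of 1. Fewer than 1 such gene was expected near Sox2, so finding 0 decides nothing, and the bound set beforehand, a share at most 1.5 times that of other genes, was met by too few genes to count against such a block.

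The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes past the adjusted threshold as in the real split (0) came in 10 of 10 splits, with 13 as the highest other. For genes at an unadjusted p under 0.05, 7 splits gave as many as the real 354, and the highest other gave 1484. For gene lists past the threshold, 4 splits gave as many as the real 10, and the highest other gave 13. For genes apart with a fold of at least 1.5, 5 splits gave as many as the real 101, and the highest other gave 407. The split of control replicate 1 with Sox2cKO replicates 1 and 2 from the rest called 13 genes, among them the cornification genes Dsc1 and Rptn, and that with Sox2cKO replicates 1 and 3 called 5. Both keep the 2 high-Xist arrays together, and none of these genes lies on X or Y. These splits were singled out for their counts, and what divides the arrays in this way was not tested. The 4 splits that part all 3 replicate pairs include the real one, and the others gave 254 to 383 genes at an unadjusted p under 0.05, 6 to 9 lists and 53 to 97 genes apart.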
